A study of Mus musculus with 2 samples.

How the data were processed

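The series holds 2 two-colour Agilent expression arrays of mouse RNA. Each array carried RNA from a mouse lung sample that had not been cultured, labelled with Cy3, and RNA from mouse embryonic fibroblasts (MEF) grown in serum-containing medium, labelled with Cy5, per the labels. MEFs are fibroblast cultures derived from embryos and served as the control. The labels number the lung samples 1 and 2, and do not say whether they came from separate animals. The p-values of single genes therefore rest only on the spread between these 2 samples, the gene's own combined with that pooled over all genes. That spread may be technical. Whether both arrays received the same MEF preparation is not stated either. The dyes were not swapped, so any dye effect stays in every ratio, and the number of arrays limits the precision.

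The authors deposited 1 table with a log ratio per probe and array. Agilent Feature Extraction is named as the software, per the submitters' processing notes, and its version, background correction and dye normalization are not given in the sources used here. The deposited table lists 41174 probes with 2 values each, none missing and none at exactly 0, and no control features. Neither the base of the logarithm nor the direction of the ratio is stated. The deposited values reach 10.1 in size, which as base-10 logarithms would be ratios far beyond the range of a scanner, so they were read as log2 ratios. Natural logarithms are not excluded by the table, and with that base the folds given here would be larger. The medians over all probes were -0.28 for lung replicate 1 and -0.14 for lung replicate 2, so the columns were not centred on a median of 0. Channel intensities, background flags and saturation flags were not used here, so it is not known which ratios rest on a dim or saturated channel.

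The direction was set by a rule fixed before the data were examined. A list of 12 lung-restricted genes (surfactant proteins and club cell secretory genes, called the orientation list) had to show 1 sign in at least 80% of its values, and that sign was called higher in lung. All values of the 11 measured members were above 0, so positive values are given as lung over MEF. This direction rests on the assumption that these genes are higher in lung than in fibroblasts, and is opposite to Agilent's convention of Cy5 over Cy3. With it assumed, the values of the orientation genes are no finding, and were the assumption wrong every higher and lower would be exchanged.

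Probes were named through a table of the platform's annotation, and symbols were checked against a RefSeq gene table by Entrez identifier. Of the probes, 32664 carried 1 gene symbol, 45 carried several and 8465 carried none. Probes of a gene were averaged on each array, which gave 19532 genes, 8511 of them with more than 1 probe. For 320 of these genes, probes lay at least 2-fold above and at least 2-fold below 0, so their mean is uncertain. No genome positions are printed, since no build is named for the array design.

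Each gene's log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept-only fit with eBayes, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The control was present only as the reference channel, so the test leaves out the spread between MEF cultures. Each gene had 1 residual degree of freedom, to which the moderation added 1.21. Genes at least 2-fold apart (a log2 ratio of 1 or more in size) in the same direction on both arrays were counted without a test. The test was tried on simulated data built from the estimated spread, with 200 of 19532 genes changed. It recovered 0 of 50 genes changed by 0.5, 0 of 50 changed by 1, 26 of 50 changed by 2 and 35 of 50 changed by 4 on the log2 scale, with 4 false calls. The simulated noise and the recovery required of this test were both eased after a first run fell short of the recovery first required. These shares are therefore no pass mark. They describe the test where 200 genes change, and not its sensitivity in the real table. Far more genes differed there, which relaxes the unadjusted p needed. Of the 3341 genes at least 2-fold higher and 2999 at least 2-fold lower in lung on both arrays, 3331 and 2993 passed.

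Before the data were examined, 41 gene lists were fixed, covering lung cell types, blood cells, other tissues, culture, growth, metabolism and development. Shifts of the 40 lists other than the orientation list were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. With the preset correlation, camera sets a list against the spread across genes. Its p-values then do not measure the spread between samples. Member counts adjusted over the list alone equalled those adjusted over all genes for 36 of the 40 lists and differed by 1 gene in the rest, which are given with their lists. The genes named are the orientation list, the 15 genes highest and the 15 lowest by mean log2 ratio among those past the test with arrays less than 1 apart (leaving out clone and model names), up to 4 members of largest size in each list, and 6 reprogramming genes. Any other gene named was chosen after its values were seen, and this is said where it occurs.

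Alternatives planned beforehand were median centring, quantile normalization between arrays, single probes, the first probe of each gene, leaving out probes at the extremes, other variance models, other thresholds, the other log base, an estimated correlation and ranks for the lists, and leaving out each array. After the data were examined, a comparison with olfactory and vomeronasal receptor genes was added as a gauge of ratios without transcript, together with centring on those genes, a reading as natural logarithms and the removal of probes in a pile-up of values. Centring would shift the gene values away from gene medians of -0.22 on lung replicate 1 and -0.14 on lung replicate 2, and all values below are on the deposited scale.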

Results

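Expression in uncultured mouse lung was compared with that in cultured mouse embryonic fibroblasts (MEF), to describe how the 2 differ. The data comprised 2 lung samples, each hybridised against MEF RNA on an array of its own, and 19532 genes with a log2 ratio of lung over MEF on both. The arrays agreed closely. Across genes, which are not independent replicates, Pearson's r was 0.98 and Spearman's rho was 0.96. Each ratio was taken over MEF RNA, so the agreement may partly be that of the reference. The SD of the difference between the arrays was 0.31, and 94.1% of genes had the same sign on both. No probe had identical values on both arrays. Only 363 genes (1.86%) differed by more than 1 between the arrays.

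Uncultured lung and MEF differed in a large part of the transcriptome. On both arrays, 3341 genes were at least 2-fold higher in lung and 2999 were at least 2-fold lower. Read as natural logarithms, 4185 were higher and 4618 lower, so which direction held more genes depends on the base. Only 2 genes were 2-fold apart in opposite directions, Cd276 (2.26 on lung replicate 1 and -4.05 on lung replicate 2) and Kbtbd8 (1.26 and -1.82). By limma's moderated test, 6366 genes were higher and 8514 lower in lung at an adjusted p below 0.05, which is 76.2% of those tested. Of these calls 42.8% were higher in lung. With each array centred on its median the share was 51.3%, and with each array centred on the olfactory and vomeronasal receptor genes it was 63.6%. Without moderation 2448 genes were higher and 3164 lower. Tested against a 2-fold change, 2754 were higher and 2242 lower, so the number and balance of calls depend on the test. The olfactory and vomeronasal receptor genes, which are normally transcribed in sensory epithelia, numbered 1046, and 58.5% of them also passed the moderated test against 0. Their central 95% ran from -1.36 to 1.06 in the mean log2 ratio, and 8.89% of them were 2-fold apart on both arrays against 32.5% of all genes. Across these receptor genes the arrays correlated with r = 0.80. Passing the test is therefore given below together with the size of the ratio, and "the receptor range" means the central 95% of these genes on each array. It ran from -1.39 to 1.22 on lung replicate 1 and from -1.45 to 1.23 on lung replicate 2. A gene counted as above or below it lay there on both arrays. Of all genes, 2854 lay above it and 1714 below. Cd276, Kbtbd8 and list members named below as exceptions to their list were chosen after their values were seen.

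**Figure D1:**
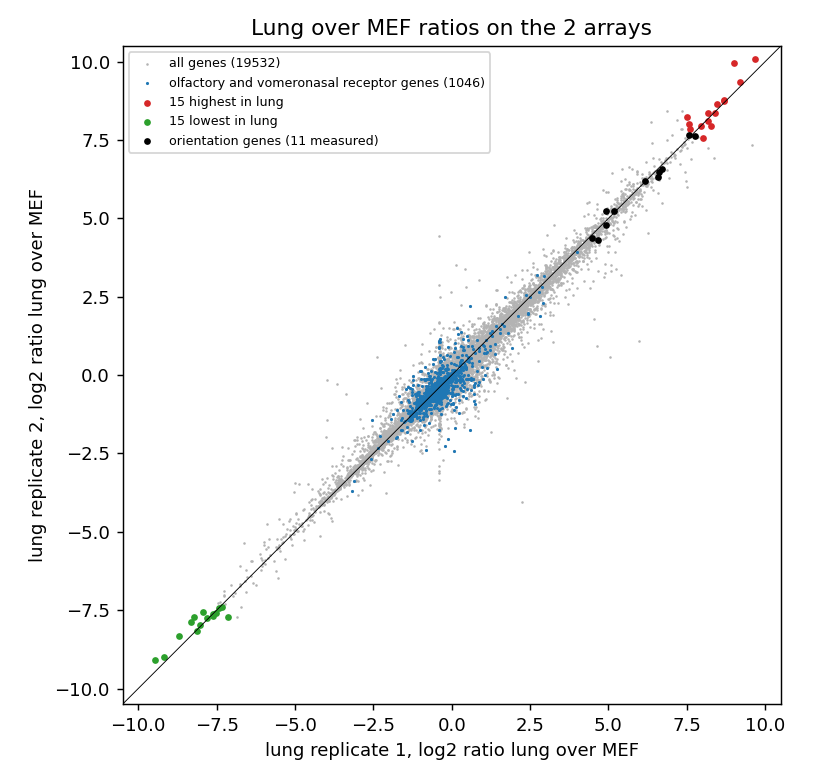
Log2 ratio of lung over MEF on lung replicate 1 (x axis) against lung replicate 2 (y axis), with 1 dot per gene, for 19532 genes. Coloured dots mark 1046 receptor genes, the 15 highest and 15 lowest named genes and the 11 measured orientation genes, and the line marks equal values. The arrays follow the line with r = 0.98, and the receptor genes cluster near a median of -0.42.

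The 15 genes highest in lung by the naming rule had mean log2 ratios from 7.73 to 9.88. S100a8, a calcium-binding protein abundant in neutrophils, had the highest log2 ratio at 9.88 ± 0.28 (SD, n = 2), or 941-fold. Il18r1, a subunit of the interleukin-18 receptor, followed at 9.49 ± 0.68, and the eosinophil-associated ribonuclease Ear10, whose family holds near-identical copies that a probe may not separate, at 9.27 ± 0.11. S100g, a calcium-binding protein, and the carboxylesterase Ces1d both reached 8.72, and the antimicrobial lectin Reg3g reached 8.56. Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, was 309-fold higher (8.27 ± 0.14). Cyp2a5, which also has a close paralog, was at 8.13. The vascular cadherin Cdh5 was 246-fold higher (7.95 ± 0.01), with its 2 probes at 6.13 and 9.76, and the endothelial carbonic anhydrase Car4 was 221-fold higher. Itprid1 (8.37), Sec14l4 (8.11), Akap14 (7.86), the chloride channel gene Clic5 (7.79) and the muscle mitochondrial creatine kinase Ckmt2 (7.73) completed the 15 highest. Their adjusted p by limma with Benjamini-Hochberg adjustment was at most 0.00263.

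The 15 genes lowest in lung by the same rule had mean log2 ratios from -9.27 to -7.36. Cpa6, a carboxypeptidase, had a log2 ratio of -9.27 ± 0.26 and was 618-fold lower in lung, and the secreted growth factor Ptn (pleiotrophin) was 542-fold lower at -9.08 ± 0.12. The transcription factor genes Zic1 (-8.51), Hoxc9 (-8.14), Hoxb9 (-8.09) and Foxd1 (-7.96) were 249- to 365-fold lower. Rspo2, an enhancer of Wnt signalling, stood at -8.00, the BMP antagonist Grem1 at -7.78, and Spock3 at -7.74. The matrix genes Fbln2 (fibulin-2) and Col1a1 (the alpha-1 chain of type I collagen) were 199.8- and 197-fold lower, and the tendon glycoprotein gene Tnmd was 188-fold lower. The fetal growth factor Igf2 (-7.44 ± 0.01), Rtl3 (-7.43 ± 0.41) and the oncofetal RNA-binding protein gene Igf2bp3 (-7.36 ± 0.05) completed the 15 lowest. Their adjusted p by limma with Benjamini-Hochberg adjustment was at most 0.00212.

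Of the 40 gene lists tested, 17 were higher in lung and 12 lower relative to all other genes by camera with the preset correlation. Those p-values rest on the spread across genes and not on that between samples. With a correlation estimated from the data, which leaves 1 degree of freedom, 0 lists passed: the lowest adjusted p was 0.389, and 0 passed at an unadjusted p below 0.05 (lowest 0.0917).

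**Figure D2:**
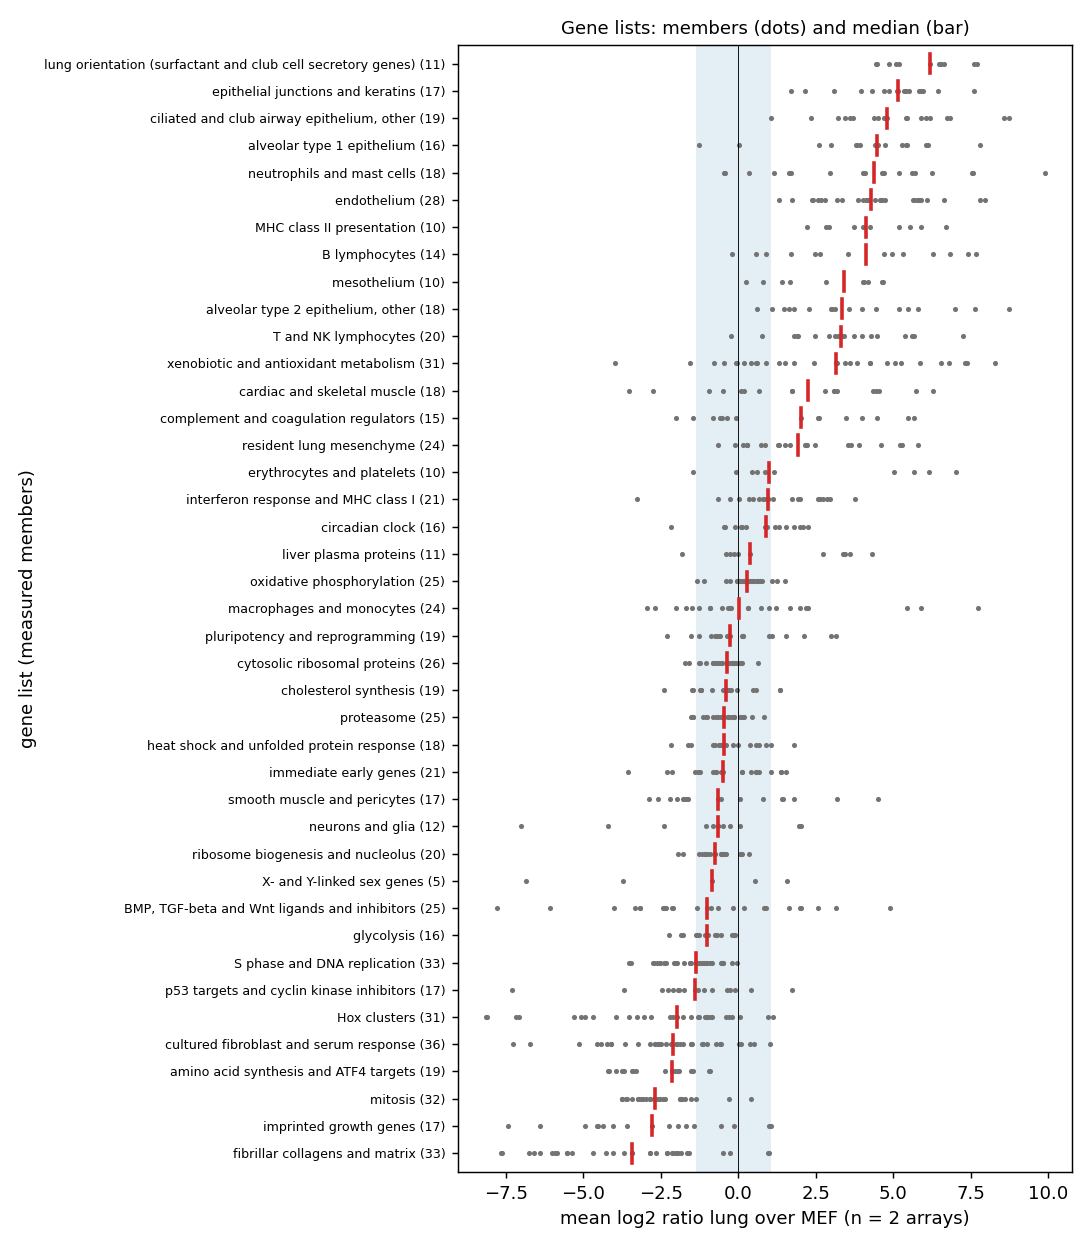
Mean log2 ratio of lung over MEF (x axis, n = 2 arrays) of each measured member (grey dots) of the 41 gene lists (y axis, number measured in parentheses), with the list's median as a red bar and the receptor genes' central 95%, from -1.36 to 1.06, shaded. The medians of the epithelial, endothelial, neutrophil and lymphocyte lists lie to the right of the shaded range, and those of the collagen, imprinted and mitosis lists to its left. The shading is for the mean of the arrays, whereas counts in the text use the range on each array.

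Epithelial genes of the airways and alveoli were much higher in lung. The orientation genes, which set the sign of the ratio and so are no finding, ranged from 4.43 for Sftpb to 7.70 for Sftpd. Among them, Sftpc was at 6.55, Sftpa1 at 5.19, Scgb1a1 at 6.64, Scgb3a1 at 6.18, Cyp2f2 at 7.61, Napsa at 6.46, Ager at 5.08, Slc34a2 at 4.86 and Lamp3 at 4.48. All 17 measured members of the list of epithelial junctions and keratins were higher and outside the receptor range, with a median of 5.14. They included the adhesion genes Epcam (7.60 ± 0.36) and Cdh1 (6.44 ± 0.02), the keratin gene Krt8 (5.97) and the transcription factor gene Elf5 (5.89). All 19 measured genes of ciliated and club cells were higher (median 4.81), among them the dynein light chain gene Dynlrb2 at 6.81 and the glutathione transferase gene Gsta3 at 6.74. Of 18 further type 2 cell genes, 18 were higher (median 3.35), with the lung transcription factor Nkx2-1 at 7.63 ± 0.10, the chemokine Cxcl15 at 6.97 and the ion transporter Slc26a9 at 5.81. This list shares Sftpa1 with the orientation list. Type 2 and club cell genes mark the same cells as orientation genes, so their direction largely follows from the sign rule and is no separate finding. Of 16 type 1 cell genes, 14 were higher (median 4.47), including Hopx (6.12), the scaffold gene Akap5 (6.06) and the water channel Aqp5 (5.43). Of the other 2, Pdpn was lower at -1.27 and Igfbp2 was at 0.01. Camera gave these 4 lists adjusted p-values of 1.69e-06 or lower, and each had adjusted p = 0.389 with an estimated correlation. Above the receptor range lay 18 of the 19 ciliated and club cell genes, 16 of the 18 type 2 cell genes and 14 of the 16 type 1 cell genes.

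Endothelial genes were higher in lung without exception among the 28 measured. Their median log2 ratio was 4.29, and 27 lay above the receptor range. Besides Cdh5 and Car4, Tmem100 was at 6.62 ± 0.45 and the tight junction gene Cldn5 at 6.09 ± 0.01. The list had the lowest camera p, 3.33e-11 after adjustment, and adjusted p = 0.389 with an estimated correlation. Genes of the resident lung mesenchyme were also higher, 22 of 24 with a median of 1.91, although the reference was itself mesenchymal. The transcription factor Tcf21 stood at 5.80 ± 0.05, the methyltransferase Inmt at 5.27, the guanylate cyclase subunit Gucy1a1 at 5.23 and the aminopeptidase Enpep at 4.60. Scara5 was lower at -0.65. Mesothelial genes were higher in 9 of 10 (median 3.42), with Upk1b at 4.65, Msln (mesothelin) at 4.64, Upk3b at 4.18 and Lrrn4 at 4.05. These 2 lists had camera adjusted p-values of 6.60e-07 and 1.56e-04, and adjusted p = 0.389 with an estimated correlation for both. Above the receptor range lay 16 of the 24 mesenchymal and 8 of the 10 mesothelial genes. Smooth muscle and pericyte genes split, with 6 higher and 10 lower of 17 and no list shift (camera adjusted p = 0.557). Phospholamban (Pln, 4.50) and the potassium channel gene Kcnj8 (3.17) were higher, while transgelin (Tagln, -2.89) and Rgs5 (-2.58) were lower.

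The lists of neutrophil, lymphocyte and MHC genes were higher in lung, whereas macrophage genes went both ways. Of 18 neutrophil and mast cell genes, 15 were higher (median 4.37), with Retnlg at 7.58, S100a9 at 7.53 and the collagenase Mmp8 at 6.24 beside S100a8. The mast cell genes Ms4a2 (-0.47) and Tpsb2 (-0.42) were lower within the receptor range. Of 20 T and NK cell genes, 19 were higher (median 3.30), including the NK receptor Klrd1 (7.25 ± 0.09), granzyme A (Gzma, 5.66), Cd8b1 (5.61) and the T cell receptor component Cd3d (5.36). Of 14 B cell genes, 12 were higher (median 4.12), led by Fcrla (7.65), the immunoglobulin joining chain Jchain (7.41), Cd79b (6.83) and Fcmr (6.28). All 10 genes of MHC class II presentation were higher (median 4.13), with H2-Aa at 6.71, Cd74 at 5.88, H2-Ab1 at 5.52 and H2-DMb2 at 5.19. The class I and interferon list had 17 of 21 higher and 3 lower, with the immunoproteasome subunit Psmb9 at 3.78, H2-K1 at 2.97 and H2-D1 at 2.85, while Isg15 (-3.27 ± 0.0047), Irf7 (-0.67) and Ifit2 (-0.26) were lower. Camera's adjusted p was 7.62e-05 or lower for these 5 lists. With an estimated correlation it was adjusted p = 0.399 for T and NK cells and adjusted p = 0.389 for the other 4. Above the receptor range lay 14 of the 18 neutrophil and mast cell genes, 18 of the 20 T and NK cell genes, 11 of the 14 B cell genes, all 10 class II genes and 9 of the 21 class I and interferon genes. Probes of MHC genes may share signal between near-identical family members. Macrophage and monocyte genes went both ways, with 12 higher and 12 lower, a median of 0.03 and no list shift (camera adjusted p = 0.465). Of these 24 genes, 7 lay above the receptor range and 4 below it. Chil3 (7.72), the chemokine receptor Ccr2 (5.89) and Plet1 (5.44) were higher, and the complement gene C1qa was lower at -2.95 ± 0.01. Blood transcripts were present in the lung samples: of 10 erythrocyte and platelet genes 7 were higher and 1 lower, with alpha globin (Hba-a1) at 7.03 ± 0.13, Gp9 at 6.14, Alas2 at 5.67 and Ppbp at 5.02, and Gp1bb lower at -1.47. That list had a camera adjusted p of 0.00558, and adjusted p = 0.389 with an estimated correlation, and 4 of the 10 lay above the receptor range.

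Matrix genes and genes of fibroblasts in culture were lower in lung. Of 33 matrix genes, 30 were lower with a median of -3.42, and 29 lay below the receptor range. Beside Col1a1 and Fbln2, the cross-linking enzyme Lox stood at -6.74 ± 0.24 and thrombospondin 2 (Thbs2) at -6.59 ± 0.01. The 2 members that were higher were Dcn (decorin, 0.99) and Timp3 (0.96), neither of them above the receptor range. Of 36 genes of cultured fibroblasts and the serum response, 31 were lower and 3 higher (median -2.10). The mesenchymal transcription factors Twist1 (-7.28 ± 0.63) and Prrx2 (-6.71) and the chemokines Ccl2 (-5.14) and Ccl7 (-4.55) were the most different. Mmp3 (1.02), Hbegf (0.51) and Pdgfra (0.36) were higher, none of them above the receptor range. Both lists passed camera (adjusted p = 5.35e-07 and 1.82e-05), each with adjusted p = 0.389 with an estimated correlation. Of the cultured fibroblast genes, 25 of 36 lay below the receptor range.

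Genes of cell division were lower in lung. Of 32 mitosis genes, 30 were lower (median -2.70), with Pbk, Tpx2, Ttk and Kif20a between -3.77 and -3.63, or 12.4- to 13.6-fold. Ndc80 was higher at 0.41, which is not above the receptor range. Of 33 genes of S phase and DNA replication, 31 were lower and 0 higher (median -1.35), with the cyclin genes Ccne1 (-3.53) and Ccne2 (-2.75), the helicase component Gins2 (-3.47) and thymidine kinase Tk1 (-2.73) furthest. Camera gave adjusted p-values of 4.38e-07 and 9.98e-07. With an estimated correlation, adjusted p = 0.389 for mitosis and adjusted p = 0.518 for S phase. Below the receptor range lay 28 of the 32 mitosis genes but 15 of the 33 S phase genes. Inhibitors of the cell cycle and p53 targets were lower as well, 13 of 17 (14 when adjusted over the list alone) with 2 higher. Cdkn2a, which encodes p16 and p19, was 159-fold lower in lung (-7.31 ± 0.11) and Cdkn1a, which encodes p21, was lower at -3.70. Ccng1 was at -2.47 and Zmat3 at -2.26, while Perp (1.72) and Cdkn2c (0.41) were higher. This list had a camera adjusted p of 0.00422, and adjusted p = 0.389 with an estimated correlation, and 8 of the 17 lay below the receptor range. Immediate early genes split into 7 higher and 11 lower, with 3 above and 3 below the receptor range. Egr1 (-3.56), Myc (-2.29) and Ier2 (-2.14) were lower and Klf4 (1.52) was higher. Their median was -0.50 while camera's direction was upward, with adjusted p = 0.988.

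The list of xenobiotic and antioxidant metabolism was higher in lung, whereas the lists of amino acid synthesis and glycolysis were lower. Of 31 genes of xenobiotic and antioxidant metabolism, 24 were higher and 4 lower (median 3.17). Cyp2b10 (7.38 ± 0.18), Cyp4b1 (7.31) and the sulfotransferase gene Sult1a1 (6.81) followed Cyp1a1, while Cyp1b1 (-3.97), heme oxygenase (Hmox1, -1.54) and the metallothionein genes Mt1 (-0.78) and Mt2 (-0.45) were lower. All 19 genes of amino acid synthesis and the ATF4 response were lower (median -2.15), including Trib3 (-4.20), the mitochondrial folate enzyme Mthfd2 (-4.18), the serine synthesis gene Psat1 (-3.93) and Aldh18a1 (-3.76). Of 16 glycolysis genes, 14 were lower and 0 higher (median -1.02), with the lactate transporter Slc16a3 at -2.23, Pgk1 at -1.86, Pgam1 at -1.79 and Pfkl at -1.36. Only 3 of these 16 lay below the receptor range, as did 16 of the 19 amino acid genes, and 20 of the 31 xenobiotic genes lay above it. Camera's adjusted p was 2.27e-06, 8.95e-06 and 4.10e-04 for these lists in turn. With an estimated correlation, adjusted p = 0.389 for the xenobiotic and glycolysis lists and adjusted p = 0.393 for the amino acid list.

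Shifts of basic cellular machinery were small. Of 25 genes of oxidative phosphorylation, 16 were higher and 4 lower (median 0.30), with Cox6c 2.83-fold higher and Ndufb3 at 1.26 against Sdhb at -1.32, Atp5b at -1.12, Uqcrc1 at -0.40 and Ndufs1 at -0.25. Of 20 genes of ribosome biogenesis, 16 were lower (median -0.76), with Gnl3 at -1.95, Wdr12 at -1.78, Fbl at -1.25 and Npm1 at -1.18, and Pes1 higher at 0.33. Of 26 cytosolic ribosomal protein genes, 19 were lower (median -0.35), although the median turned to 0.06 when the arrays were centred on the receptor genes. The lowest were Rplp0 (-1.71), Rpl4 (-1.59), Rps2 (-1.26) and Rps20 (-1.23), Rps24 was higher (0.62), and 1 of the 3 Rps2 probes pointed the other way at 0.82. Of 25 proteasome genes, 17 were lower (median -0.46, and -0.04 with receptor centring), with Psmb7 at -1.52, Psma4 at -1.45, Psmd14 at -1.44 and Psmc3 at -1.14, and Psma3 (0.82), Psma1 (0.44) and Psma7 (0.18) higher. Camera's adjusted p-values were 0.00539, 0.0114, 0.0197 and 0.0266 for these 4 lists. With an estimated correlation, adjusted p = 0.501 for oxidative phosphorylation and adjusted p = 0.389 for the others, and the ribosomal protein and proteasome lists also lost their calls with median centring (adjusted p = 0.0970 and 0.0748). Outside the receptor range in the direction of their list lay 2 of the 25 genes of oxidative phosphorylation, 2 of the 20 of ribosome biogenesis, 2 of the 26 ribosomal protein genes and 1 of the 25 proteasome genes. Cholesterol synthesis genes had 14 of 19 lower and a median of -0.39, which turned to 0.02 with receptor centring, and did not pass (camera adjusted p = 0.0660), although they passed as lower with camera on ranks (adjusted p = 0.0400). Cyp51 (-2.38), Mvk (-1.48) and Hsd17b7 (-1.45) were lower and Ebp (1.35) was higher. Of the 19 genes, 2 lay above the receptor range and 2 below it. Genes of heat shock and the unfolded protein response split into 6 higher and 11 lower without a list shift (camera adjusted p = 0.554), with Herpud1 at 1.80 against Ddit3 at -2.17, Calr at -1.62 and Hspd1 at -1.52. Of these 18 genes, 1 lay above the receptor range and 3 below it. Clock genes were higher in 10 of 16 and lower in 2 (3 when adjusted over the list alone), with a camera adjusted p of 0.00992 and adjusted p = 0.389 with an estimated correlation, and 6 of the 16 lay above the receptor range. Ciart (2.26), Tef (2.07) and Hlf (1.99) were higher and Arntl, which encodes the activator BMAL1, was lower (-2.18 ± 0.04), as was Bhlhe41 (-0.47). Complement and coagulation genes had 8 higher and 6 lower of 15 (camera adjusted p = 0.182), led by C4b (5.66), Hc (5.46), Cfb (4.47) and Serping1 (3.98). Of these 15, 8 lay above the receptor range and 2 below it.

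Hox genes and imprinted growth genes were lower in lung as lists. Of 31 Hox genes, 27 were lower (28 when adjusted over the list alone) with a median of -1.99. Beside Hoxc9 and Hoxb9, Hoxa11 stood at -7.16 ± 0.16 and Hoxc6 at -7.07 ± 0.49. The 2 Hox genes that were higher were Hoxb5 (1.13) and Hoxa5 (0.96), both within the receptor range. Imprinted growth genes were lower in 14 of 17 (median -2.77), with H19 at -6.39 ± 0.26, Mest at -4.93 and Peg3 at -4.54 after Igf2. Nnat (1.06) and Dcn were higher, neither of them above the receptor range. Camera's adjusted p was 1.23e-04 for Hox genes and 0.00269 for imprinted genes, with adjusted p = 0.397 and adjusted p = 0.389 with an estimated correlation. Below the receptor range lay 18 of the 31 Hox genes and 12 of the 17 imprinted genes. Ligands and inhibitors of the BMP, TGF-beta and Wnt pathways went both ways, with 9 higher and 16 lower of 25 (camera adjusted p = 0.333). Wnt3a was higher at 4.90 ± 0.08, while Grem1, the activin subunit Inhba (-6.07) and Dkk2 (-4.02) were lower.

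The list of pluripotency and reprogramming genes did not shift (8 higher, 9 lower of 19, camera adjusted p = 0.785), and its median of -0.26 and its mean of 0.16 differed in sign, as did its median with receptor centring (0.15). Of the 19, 4 lay above the receptor range and 2 below it. Tbx3 (3.16 ± 0.10) and Klf5 (3.01 ± 0.06) had the largest ratios. Sox2 was 4.34-fold higher in lung (2.12 ± 0.14) and Klf4 was 2.88-fold higher (1.52 ± 0.10), whereas Myc was 4.88-fold lower (-2.29 ± 0.08, with 3 probes between -2.37 and -2.17). Pou5f1 (-0.88 ± 0.09), Nanog (-0.58 ± 0.24) and Lin28a (1.00 ± 0.20) passed limma's test (adjusted p = 0.0055, 0.0423 and 0.0118) with ratios within the receptor range.

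Markers of other tissues were mixed. Of 18 genes of heart and skeletal muscle, 12 were higher (13 when adjusted over the list alone) and 3 lower, with a camera adjusted p of 0.00190 and adjusted p = 0.389 with an estimated correlation, and 11 of the 18 lay above the receptor range and 2 below it. The atrial light chain gene Myl7 stood at 6.30 ± 0.03, sarcolipin (Sln) at 5.73, the cardiac myosin gene Myh6 at 4.55 and cardiac troponin I (Tnni3) at 4.44. The actin genes Acta1 (-3.52) and Actc1 (-2.75) and the fast troponin gene Tnnt3 (-0.93) were lower. Plasma protein genes of the liver did not shift as a list (6 higher and 2 lower of 11, camera adjusted p = 0.120), although Ahsg (4.30), Fgg (3.59), Trf (3.44) and Alb (3.39) were higher and Ambp (-1.82) and Fga (-0.39) lower. Genes of neurons and glia had 2 higher and 9 lower of 12 (camera adjusted p = 0.199), with Fabp7 at -7.01 ± 0.06, Gfap at -4.20 and Nefm at -2.40, while Mbp was at 2.01 with 1 of 3 probes at -0.46. Only 3 of these 12 lay below the receptor range, and 2 lay above it. Among sex-linked genes, the Y-linked Eif2s3y was 116-fold lower in lung (-6.86 ± 0.25), Kdm5d was at -3.73 ± 0.57 and Uty was at -0.86 ± 0.30. The 4 Uty probes ran from -2.79 to -0.12. The X-linked Tsix was at 1.56, and Xist was at 0.54. The list pools X- and Y-linked genes, whose ratios here had opposite signs. Its test of a common direction (camera adjusted p = 0.988) can cancel between them and decides for neither group.

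**Figure D3:**
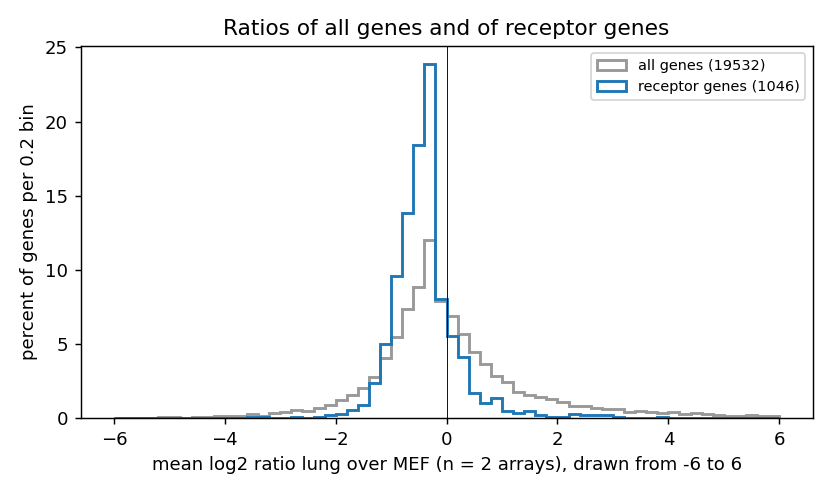
Percent of genes (y axis) per bin of 0.2 in the mean log2 ratio of lung over MEF (x axis, n = 2 arrays, drawn from -6 to 6), for all 19532 genes (grey) and the 1046 olfactory and vomeronasal receptor genes (blue). The receptor genes peak to the left of 0, with a median of -0.42.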

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

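The receptor range, receptor centring, natural logarithms and removal of piled-up probes were chosen after the data were seen. Both counts of genes stayed within 1.5 times under median centring, quantile normalization and removal of extreme or piled-up probes. The tested counts did so too under robust moderation and at an adjusted p below 0.01. Single probes in place of genes gave 10516 higher and 14043 lower by the test, 5795 higher and 5837 lower by at least 2-fold, and r = 0.978. The first probe of each gene gave r = 0.980. Without moderation the test called 2448 and 3164 genes, and against a 2-fold change 2754 and 2242. A 4-fold limit left 1767 and 911 genes. Reading the table as log10 gave 5822 and 7776 genes at 2-fold, and as natural logarithms 4185 and 4618. Against the receptor range, 2854 genes were above and 1714 below on both arrays, and centring on the receptor genes gave 9120 higher and 5224 lower. The cause was not tested for any of these. On 1 array alone, 3546 to 3607 genes were 2-fold higher and 3315 to 3337 lower, and no test can be made. List shifts numbered 0 higher and 0 lower with an estimated correlation, whose 1 degree of freedom lets hardly any list pass. They numbered 17 and 13 on ranks, where cholesterol synthesis was gained, and 17 and 10 with centring, where the ribosomal protein and proteasome lists were lost. Of 189 named genes, none changed sign or lost its call with centring, and none changed sign on either array alone. Single probes had the opposite sign to the gene's mean for Rps2 (0.82) and Mbp (-0.46), and an Atp5b probe was near 0 (5.2e-05). Another 5 single probes kept the sign but did not pass, 3 of Uty (-0.27 to -0.12) and 1 each of Peg3 (-2.31) and Tef (0.23). No paired analysis was possible because there is 1 group of samples. Which ratios rest on dim channels cannot be told without intensities.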

Other observations

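Of the tests below, those on the pile-up of values, on the macrophage genes against the receptor range and on muscle genes outside the fixed list were chosen after the values had been seen. The other gene lists used here were written before their own genes were looked up, but after the shifts of the fixed lists had been seen and, for macrophages, the values of the fixed members. The skeletal muscle list shares 7 of its 14 measured genes with the fixed heart and skeletal muscle list, and the atrial list 9 of 14. Genes of alveolar macrophages on a second list were higher in lung in 11 of 11 measured (median 2.81, 95% bootstrap interval over genes 1.29 to 5.06). They included the proton pump subunit Atp6v0d2 (5.07 ± 0.07), the lipid droplet gene Cidec (5.06 ± 0.21), the keratin gene Krt79 (3.82 ± 0.03) and the cholesterol exporter Abcg1 (2.81 ± 0.02). Of the 11, 9 lay above the receptor range, but Siglecf (0.84 and 1.24 on lung replicates 1 and 2) and Slc7a2 (0.45 and 0.55) did not. Fabp1 (9.59 and 7.34) and Trim29 (4.41 and 2.76) differed by more than 1 between the arrays. Of 9 thymus genes (median -0.10), 3 were higher, the lymphocyte genes Cd8b1 (5.61) and Cd8a (3.22) and the lipid antigen presenting gene Cd1d1 (1.91), and Psmb11 was lower (-0.36). The other 5, Rag1 (-0.10), Rag2 (-0.15), Ptcra (-0.26), Dntt (-0.09) and Foxn1 (-0.28), did not pass the test. Among the 8510 probes without a single gene symbol, 1486 were at least 2-fold higher in lung on both arrays and 843 lower.

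Macrophage genes went both ways, and C1qa (-2.95), C1qb (-2.70), Adgre1 (probes at -2.93 and -1.07) and Cx3cr1 (-1.69) were among those lower in lung. A hypothesis is that the MEF culture held macrophages, which may be carried over from the embryos. A second list of 17 tissue macrophage genes had a median of -1.44 (bootstrap interval -2.94 to -0.50), with 13 lower in lung, among them Hpgds (-3.18), Ccl4 (-3.09), Ms4a7 (-3.02) and Trem2 (-2.98), and 4 higher, Cd163 (5.78), F13a1 (1.53), Mpeg1 (1.28) and Aif1 (0.95). The offset seen in silent genes is argued against for the 8 of these 17 genes that lay below the receptor range on both arrays, against 0.228 given by the receptor genes' own share of 1.34% (exact binomial p = 2.25e-11, one-sided, taking genes as independent), and stays open for the others. Expression of these genes by the fibroblasts themselves, and a different state of the macrophages of lung, which also express them, stay open and were not tested.

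Of the 18 heart and skeletal muscle genes fixed beforehand, 12 were higher in lung and 3 lower. For skeletal muscle, 14 genes had a median of -0.43 (bootstrap interval -0.95 to 0.25), under the bound of 0.5 set beforehand. Of them 6 were lower and 4 higher, Myh4 (3.10), Myl1 (2.18), Ckm (1.72) and Tnni2 (0.25). Above the receptor range lay 3 and below it 2. The 7 genes outside the fixed list had a median of -0.87 (-1.75 to 0.25). The skeletal muscle list as a whole was thus not raised over MEF. Expression in MEF would lower these ratios whatever lung held, so skeletal muscle as a source stays open. For ventricular heart tissue, 8 genes had a median of 0.0879. The rule set beforehand against this source asked for a median under 0.5, with a median above 2 for the atrial and shared genes. Both medians met it (2.99 for the latter). The bootstrap interval of -0.78 to 1.33, which was no part of that rule, includes 0.5, so the ventricular list is taken not to decide. Of the 8 genes, Myh7 (4.48, similar in sequence to Myh6), Hey2 (1.33) and Myl3 (0.64, with probes at -1.17 and 2.45) were higher. Fhl2 (-1.81), Myl2 (-0.78) and Irx4 (-0.67) were lower. Atrial tissue and the heart-type muscle around pulmonary veins in mice stay open too and were not tested, and of 14 atrial and shared genes (median 2.99, and 0.90 over the 5 outside the fixed list) 11 were higher and Actc1 (-2.75), Nkx2-5 (-0.85) and Ankrd1 (-0.60) lower. Ankrd1 is also on the fixed list of cultured fibroblast genes, and expression in MEF would lower heart gene ratios too.

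Most genes passed the test against 0. Olfactory and vomeronasal receptor genes passed at 0.768 of the rate of all genes, 63 higher and 549 lower, and their ratios correlated between the arrays (r = 0.80 across genes). This is consistent with a reproducible offset of background, dye or probe sequence in probes without transcript, so small ratios past the test may not reflect expression. Values also piled up: 5136 probes lay between -0.44 and -0.34 on lung replicate 1 and 5040 between -0.19 and -0.09 on lung replicate 2, about 3715 and 3719 above nearby windows of equal width, and 3120 probes lay in both against 629 if unrelated. A floor value in both channels is a candidate source of that pile-up. Whether it bears on the calls stays open: the count of called genes with these probes was 0.990 of that without them, but the windows themselves hold nearly all pairs of values in them short of the test, so that ratio was set by the windows.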
